A study of Mus musculus with 9 samples.

How the data were processed

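Per the labels' protocols, B16F10 mouse melanoma cells were grown in complete medium, and total RNA of a control line, a Sirpa knockdown line and a Sirpa overexpression line was extracted. It was made into non-directional mRNA libraries and sequenced as paired-end reads of 150 bases. The labels give 3 libraries of each line as biological repeats, and all 9 were used. The kit does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart.

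The authors' files hold 1 table per library with 1 row per transcript. Per the file headers, the estimated count of each transcript is the number of fragments assigned to it and need not be whole, TPM is that value scaled by effective length to a sum of 1000000, and the effective length is given in bases. Per the submitters' processing notes, the tools were Salmon 1.4.0, MultiQC 1.11 and DESeq2 1.34.0, and the genome build was mm39. Read trimming and the annotation release are not given in the sources used here. Salmon divides fragments among similar transcripts by their estimated abundance, which leaves a gene with near-identical copies, or a single transcript of a gene, less certain than a gene total.

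The mm39 annotation was not used here. Transcript identifiers were matched to genes with the GENCODE M21 annotation of GRCm38, which served for gene names, chromosome names, the order of neighbouring genes, GC content and shared sequence, and no coordinates are given because the builds differ. Of 140789 transcripts 137161 (97.42%) matched, and the unmatched ones held 0.554% to 0.654% of the counts of a library and were left out of library sizes and tests. The deposited estimated counts were summed per gene, giving 51717 genes, and rounded to whole numbers.

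Depth ranged from 16.4 to 22.38 in units of 1000000 estimated counts per library. Replicates were compared before averaging: the chi-square per degree of freedom between pairs of libraries of a line was 4.79 to 10.64 over genes, above sampling noise in every pair, so no library was a copy of another. Groups, tests, the rule for named genes, the gene lists and the first set of alternatives were fixed before the data were examined.

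The main test was edgeR 4.0.16 (R 4.3.3), with filterByExpr, TMM normalisation and a quasi-likelihood fit to all 9 libraries with line as the only term. Of the genes, 13064 passed the filter. The 3 contrasts were knockdown against control, overexpression against control and overexpression against knockdown. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, with no fold minimum. Standard errors of log2 fold changes were derived from the fitted change and its F statistic. The levels given in CPM are counts per 1000000 with TMM library sizes, as mean ± SD of 3 libraries, and cover the spread between libraries, while floors near 0 counts cover counting error only.

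Gene lists of 2 kinds were tested, pathways (SIRP and CD47 axis, melanocyte differentiation and pigment, dedifferentiated or invasive melanoma, interferon-stimulated genes, MHC class I antigen presentation, checkpoint ligands and immune recognition, cell adhesion molecules, NF-kB targets and chemokines, MAPK pathway output, YAP and TEAD targets, extracellular matrix, mitotic genes, DNA replication and S phase, p53 targets, hypoxia and glycolysis, cholesterol synthesis, unfolded protein and ATF4 response, oxidative phosphorylation, lysosome and autophagy, heat shock genes, ribosomal proteins and mitochondrially encoded transcripts) and markers of macrophage and myeloid, T and NK, fibroblast, endothelial and epithelial cells. The 23 lists with at least 5 tested members were tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The estimated correlation of each list and fry were run beside it, and members were also adjusted over the list alone.

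The genes named in each comparison with control were Sirpa and, among called genes whose libraries of one line all lay beyond those of the other and whose mean reached 5 CPM in 1 line, the 8 largest rises and the 8 largest falls, then up to 4 members of each list with the lowest adjusted p. Between the perturbed lines the 3 largest rises and 3 largest falls were named, and among genes called in both lines the 5 in each opposite direction and the 3 in each shared direction with the largest smaller change. Predicted genes, clone names and pseudogenes were left out of naming. A gene's shared sequence is the percentage of its 31-base words, over all its annotated transcripts, that another gene also holds. It is stated for some named genes only, and a gene given without it may share sequence too.

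The steps were tested on simulated data drawn from the mean levels of the controls, the library sizes and the estimated dispersions. In each perturbed line 200 genes were changed by known folds, and 12662 genes passed the filter. For knockdown against control 55.6%, 79.4% and 90.8% of the genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 3.66% of calls were false. For overexpression against control the values were 70.8%, 80.3% and 87.7%, with 4.29% false. The p53 list was also shifted in the simulated knockdown line. The list test called that 1 list and no other of 23 there (adjusted p = 1.51e-49), and 0 lists in the simulated overexpression comparison, where none had been shifted. The simulated genes were drawn independently of one another. This run therefore cannot show how the list test behaves where members of a list are correlated.

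Alternatives were size factors by the DESeq2 method, no filter and a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, fits of the 2 groups alone, a replicate block, average transcript length from the deposited TPM values and effective lengths as an offset, leaving out each library, an adjusted p under 0.01 and a log2 fold change of at least 1. A correction for GC content and leaving out the genes of chromosomes 3 and 6 were added after seeing the data. Overlaps of calls and fold changes were compared with 20 simulations in which no gene was changed. In these all 9 libraries, controls included, were drawn anew from the mean levels of the controls and the estimated dispersions. Figures were drawn with matplotlib 3.10.9 from tables made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.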

Results

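B16F10 cells, a melanin-producing mouse melanoma line, were compared in 3 forms: a line carrying a non-targeting control, a line with knockdown of Sirpa and a line with overexpression of Sirpa. Sirpa encodes signal regulatory protein alpha, an inhibitory receptor best known from macrophages, where it binds CD47 on other cells. RNA of 3 libraries per line was sequenced, 9 libraries in all, and the comparisons ask how the transcriptome of the melanoma cells changes with less or more of this receptor. The estimated counts, in units of 1000000, summed to 16.4, 16.58 and 20.3 in the control libraries. They summed to 22.38, 16.9 and 16.54 in the knockdown libraries and to 21.4, 17.24 and 17.57 in the overexpression libraries. The labels call the 3 libraries of a line biological repeats, but each condition is 1 line. The p-values measure the spread between repeats of a line and not the spread between independently made lines. The labels do not say how the lines were made or whether they are clones or pools. Nor do they say whether the control line carries the same vector as the overexpression line, so it may not be a matched control for it.

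The libraries separated by line. The first principal component held 30.2% of the variance and placed the controls between −35.66 and −34.58, the overexpression libraries between 1.85 and 4.28 and the knockdown libraries between 27.59 and 35.09. The second component held 16.2% and set the overexpression libraries (−33.06 to −25.06) apart from all others (8.5 to 19.39). Transcripts of the mitochondrial genome made up 2.16% ± 0.019 of counts in controls, 2.48% ± 0.11 in the knockdown line and 2.42% ± 0.079 in the overexpression line (SD, n = 3 each). Ribosomal protein genes made up 4.74% ± 0.039, 4.0% ± 0.15 and 4.0% ± 0.10, and long non-coding RNAs 1.14% ± 0.032, 0.934% ± 0.015 and 1.01% ± 0.032. Of markers of other cell types, the leukocyte gene Ptprc had 0 counts in every library, while the endothelial marker Eng averaged 271, 361 and 299 CPM (counts per 1000000) in the control, knockdown and overexpression lines. Of the marker lists 6 of 13 fibroblast genes, 2 of 17 macrophage and myeloid genes, 1 of 16 T and NK cell genes, 2 of 12 endothelial genes and 1 of 12 epithelial genes were expressed highly enough to be tested. Lyz2, the lysozyme gene of myeloid cells, averaged 0.467, 1.39 and 1.79 CPM and was not called in either line against control (edgeR adjusted p = 0.129 and 0.0794). Lyz2 was called higher in both lines with the replicate block (0.0374 and 0.0176) and without control replicate 3 (0.023 and 0.0196), and with overexpression under DESeq2 (0.0366) and without a filter on low counts (0.0166).

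Sirpa (ENSMUSG00000037902) followed the labels in every library. It stood at 292.5, 289.2 and 303.3 CPM in the controls, at 118.1, 112.2 and 115.1 CPM in the knockdown libraries and at 894.9, 897.9 and 913.6 CPM in the overexpression libraries. Relative to control it was 2.56-fold lower in the knockdown line (log2 fold change −1.36 ± 0.04, SE; adjusted p = 4.57e-13, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and 3.06-fold higher in the overexpression line (1.61 ± 0.04; adjusted p = 4.7e-14), and the perturbed lines were 7.83-fold apart. The family members Sirpb1a, Sirpb1b and Sirpb1c had 0 counts in all 9 libraries. Cd47, the ligand, was at 35.2 ± 1.9, 38.7 ± 3.3 and 36.1 ± 0.95 CPM and was not called in either line (adjusted p = 0.203 and 0.798).

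**Figure D1:**
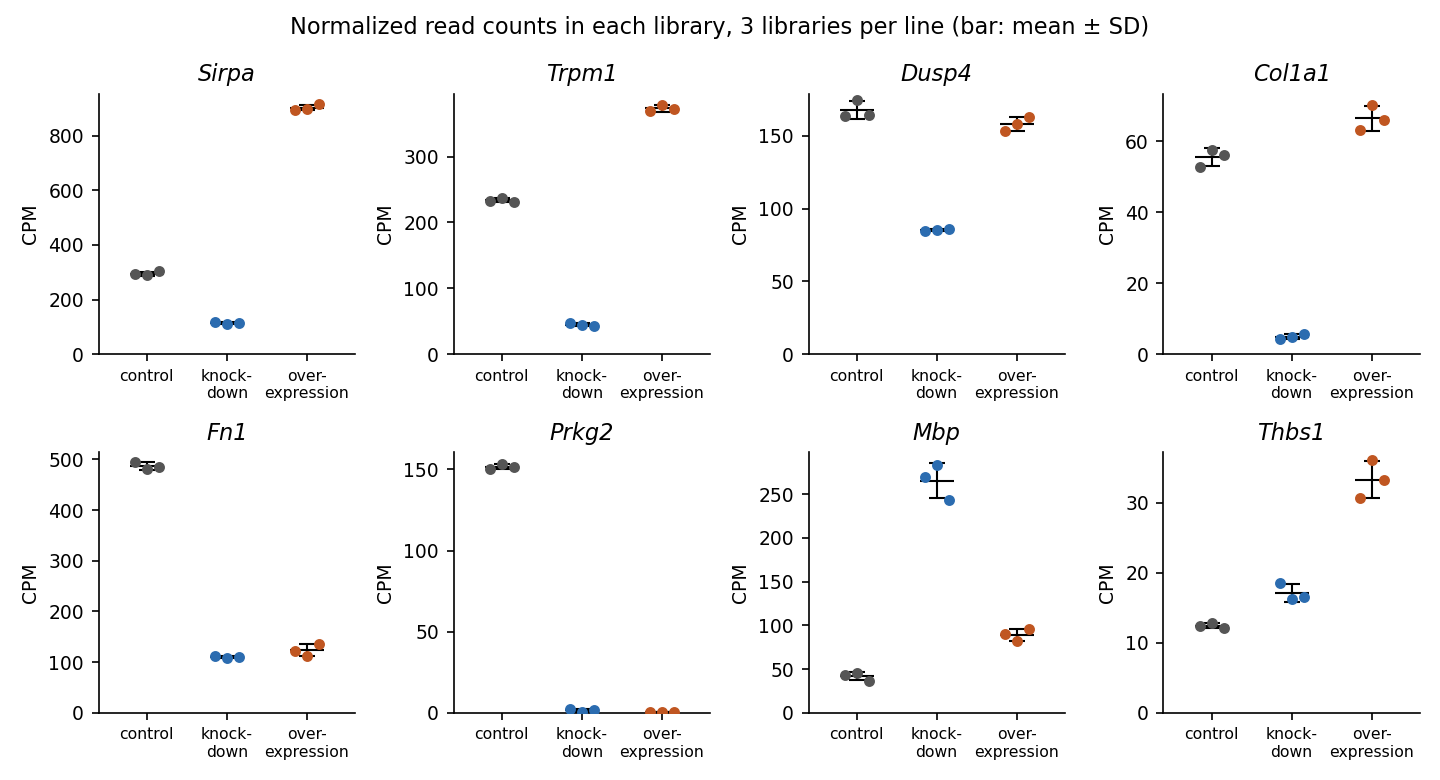
Each panel plots 1 gene, with normalised read counts in CPM on a linear vertical axis starting at 0 and the 3 lines on the horizontal axis; points are single libraries and bars the mean ± SD of 3 libraries. Sirpa averaged 295, 115 and 902 CPM in control, knockdown and overexpression. Trpm1 moved the same way as Sirpa (234, 44.8 and 374 CPM), and Prkg2 was high in controls alone (152, 1.53 and 0.572 CPM).

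Knockdown of Sirpa was accompanied by loss of several genes that control cells expressed well. Rasgrp1, which activates Ras proteins in response to diacylglycerol, fell from 60.5 ± 2.9 CPM to 0.080 ± 0.092 CPM (SD, n = 3; log2 fold change −9.29 ± 0.27, SE; adjusted p = 5.0e-13), a total of 5 counts in the 3 knockdown libraries. The imprinted non-coding RNA H19 fell from 29.6 to 0.116 CPM (−7.80 ± 0.35) and Prkg2, a cGMP-dependent protein kinase, from 152 to 1.53 CPM (−6.57 ± 0.16). For Rasgrp1 and H19, near 0 in the knockdown line, the SE derived from the F statistic understates the uncertainty of the fold. Among rises, Mbp, which encodes myelin basic protein, went from 41.8 ± 4.5 to 266 ± 20 CPM (2.67 ± 0.08; adjusted p = 7.1e-13). In total 4619 of 13064 tested genes (35.4%) differed from control, 2345 higher and 2274 lower, with a median absolute log2 fold change of 0.39 among them. Of these 603 differed at least 2-fold (284 higher, 319 lower).

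The other large falls were in the cadherin gene Cdh6 (−4.39 ± 0.34), the metalloprotease gene Adam12 (−4.33 ± 0.13; 69.4 to 3.45 CPM), the butyrophilin gene Btn2a2 (−4.10 ± 0.30), the nerve growth factor receptor gene Ngfr (−4.08 ± 0.38) and the collagen gene Col2a1 (−4.04 ± 0.63), with adjusted p-values from 5.01e-13 to 0.0001. Within the limits set for naming, the largest rise was in Sec16b, which acts at endoplasmic reticulum exit sites (3.36 ± 0.25; 1.81 to 18.4 CPM; adjusted p = 3.76e-08). It was followed by the complement protease gene C1s1 (2.90 ± 0.25), Itm2a (2.85 ± 0.34), the synapsin gene Syn1 (2.70 ± 0.25), the interferon-inducible Trim30a (2.67 ± 0.22) and the cochlin gene Coch (2.64 ± 0.32), all from 1.21 to 2.70 CPM in controls. Pagr1a rose too (3.18 ± 0.68; adjusted p = 0.00173), but it shares 93.2% of its 31-base words with Gm42742 and its value is uncertain. The value of C1s1, which shares 47.6%, largely with C1s2, is uncertain too.

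Melanoma state genes fell in the knockdown line. For each fixed list below, counts are of members called over all genes tested, and the count adjusted over the list alone is given where it differed. Of 11 tested genes of dedifferentiated or invasive melanoma, 10 fell and 1, Ccn1, rose (camera adjusted p = 8.1e-07). The falls included the fibronectin gene Fn1 (−2.14 ± 0.05, adjusted p = 1.49e-13), the receptor kinase gene Axl (−2.07 ± 0.12) and Loxl2 (−1.21 ± 0.12, with 46.4% of its sequence words shared with other genes). Of 19 tested melanocyte differentiation and pigment genes 11 fell and 4 rose, and the list was called lower (adjusted p = 0.0119; adjusted p = 0.179 with an estimated correlation). Lower were the channel gene Trpm1 (−2.38 ± 0.05; 234 to 44.8 CPM; adjusted p = 4.79e-15), the melanocortin receptor gene Mc1r (−0.43 ± 0.04), the lineage transcription factor gene Mitf (−0.38 ± 0.04) and the transporter gene Slc45a2 (−0.30 ± 0.04). The 4 that rose, named after their values were seen, were Tyrp1 (0.21 ± 0.03), Rab38 (0.29 ± 0.04), Gpnmb (0.20 ± 0.03) and Met (0.14 ± 0.03).

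Genes switched on by MAPK signalling also fell: 13 of 19 were lower and 2 higher (camera adjusted p = 2.71e-05). Dusp4 and Dusp6, phosphatases that inactivate ERK and its relatives, fell by 0.97 ± 0.05 and 0.62 ± 0.05 on the log2 scale (adjusted p = 2.66e-10 and 1.9e-07), the transcription factor gene Etv5 by 1.62 ± 0.14 and the feedback inhibitor gene Spry2 by 0.91 ± 0.12. The 2 higher members were Phlda1 (0.20 ± 0.05) and Ier3 (0.55 ± 0.12).

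Targets of p53 rose, 14 of 18 with 0 lower (camera adjusted p = 8.52e-10). They were led by Trp53inp1 (141 ± 5.1 to 358 ± 19 CPM, SD, n = 3; adjusted p = 4.57e-12), the p53 ubiquitin ligase gene Mdm2 (0.79 ± 0.04), the cell cycle inhibitor gene Cdkn1a (0.64 ± 0.04) and Ccng1 (0.65 ± 0.05). Cholesterol synthesis genes rose as well, 19 of 23 with 1 lower (Insig1, −0.10 ± 0.04), with an adjusted p of 4.14e-10. Examples were Hmgcs1 (0.79 ± 0.05) and Fdps (0.51 ± 0.04, with 27.9% of its sequence words shared with other genes). Of 20 genes of the unfolded protein and ATF4 response 12 rose and 3 fell, or 4 fell adjusted over the list alone (camera adjusted p = 0.000564). The cystine transporter gene Slc7a11 (0.99 ± 0.05), Herpud1 (0.75 ± 0.04), Pdia4 (0.49 ± 0.03) and Sesn2 (0.58 ± 0.06) led the rises, and Chac1 (−0.44 ± 0.08), Slc7a5 (−0.17 ± 0.05) and Xbp1 (−0.15 ± 0.05) fell.

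MHC class I antigen presentation genes were higher, 12 of 15 with 0 lower (camera adjusted p = 5.32e-06). They included H2-D1 (0.47 ± 0.06; adjusted p = 1.05e-05), the light chain gene B2m (0.35 ± 0.05), the peptide-loading chaperone gene Tapbp (0.56 ± 0.07) and H2-Q4 (1.17 ± 0.15). H2-D1, Tapbp and H2-Q4 share 26.9%, 26.9% and 53% of their sequence words with other genes. The interferon-stimulated genes as a list were not called (11 of 29 higher and 0 lower, 12 and 0 adjusted over the list alone; adjusted p = 0.102). The guanylate-binding protein gene Gbp2 rose by 1.51 ± 0.15 (adjusted p = 1.15e-06). NF-kB targets and chemokines, 6 of 12 higher and 0 lower with Nfkb1 at 0.62 ± 0.06, were called narrowly (adjusted p = 0.0488; adjusted p = 0.192 with an estimated correlation). That call ended without control replicate 2 (0.0644) or 3 (0.0605), knockdown replicate 2 (0.0858) or overexpression replicate 3 (0.0501), and with DESeq2 size factors (0.0507), the filter of 1 CPM in 3 libraries (0.057) or the replicate block (0.0589). Lysosome and autophagy genes, 12 of 22 higher and 5 lower (7 lower adjusted over the list alone), were called higher (adjusted p = 0.0272; adjusted p = 0.0933 with an estimated correlation). The cathepsin gene Ctsb was at 0.81 ± 0.04, Gabarapl1 at 0.71 ± 0.06 and Sqstm1 at 0.37 ± 0.03 but the cholesterol carrier gene Npc2 at −0.39 ± 0.04.

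Ribosomal protein genes fell in the knockdown line, 18 of 24 with 0 higher, or 20 adjusted over the list alone (camera adjusted p = 8.52e-10; adjusted p = 0.0933 with an estimated correlation), by a median of −0.22. Rpl13 (−0.48 ± 0.04), Rpl7 (−0.40 ± 0.04) and Rps3 (−0.28 ± 0.04) were among them, and most such genes share sequence with processed pseudogenes. Mitochondrially encoded transcripts rose, 6 of 13 with 0 lower (adjusted p = 0.0104; adjusted p = 0.192 with an estimated correlation), for example mt-Co1 (0.37 ± 0.05, with 63.9% of its sequence words shared with other genes) and mt-Nd5 (0.31 ± 0.05). Both moved with the shares of counts above, 4.0% against 4.74% for ribosomal protein genes and 2.48% against 2.16% for mitochondrial transcripts. Those shares include the counts of the list members and are no separate evidence. In all 11 of 23 lists were called, 7 higher and 4 lower, and 6 of them held with an estimated correlation. With the average transcript length per library as an offset, which raised the common coefficient of variation between libraries from 0.097 to 0.165, 2771 genes were called in place of 4619.

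Overexpression of Sirpa was accompanied by near loss of Prkg2, Rasgrp1 and Ngfr. Prkg2 fell from 152 ± 1.5 to 0.572 ± 0.042 CPM (SD, n = 3; log2 fold change −8.03 ± 0.18, SE; adjusted p = 4.7e-14), Rasgrp1 from 60.5 to 0.318 CPM (−7.52 ± 0.23; adjusted p = 1.3e-12) and Ngfr from 9.99 to 0.066 CPM (−7.00 ± 0.50; adjusted p = 5.96e-08, with 4 counts in the 3 overexpression libraries). At such low counts with overexpression, the SEs of these falls understate the uncertainty of the folds. Thbs1, which encodes thrombospondin-1, a secreted ligand of CD47, rose from 12.4 ± 0.34 to 33.3 ± 2.7 CPM (1.42 ± 0.10; adjusted p = 5.55e-08). In total 3172 of 13064 genes (24.3%) differed from control, 1716 higher and 1456 lower, with a median absolute log2 fold change of 0.35. Of these 288 differed at least 2-fold (142 higher, 146 lower).

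Other large falls were in Cdh6 (−4.57 ± 0.34), the actin-binding Tagln2 (−4.18 ± 0.24), the matrilin gene Matn3 (−3.66 ± 0.23), Col2a1 (−3.32 ± 0.59) and H19 (−3.02 ± 0.22). The largest named rises apart from Sirpa were from low levels. The retinal reductase gene Dhrs3 went from 1.59 to 6.75 CPM (2.08 ± 0.26; adjusted p = 2.53e-05), Trim30a from 2.70 to 8.57 CPM (1.68 ± 0.22) and the secreted phospholipase gene Pla2g3 from 1.61 to 5.18 CPM (1.68 ± 0.30). The hyaluronan link protein gene Hapln4 went from 1.72 to 5.2 CPM (1.60 ± 0.23), the nuclear receptor gene Nr5a1 from 1.74 to 5.29 CPM (1.60 ± 0.35) and Sec16b from 1.81 to 5.42 CPM (1.60 ± 0.26). Pagr1a, with its shared sequence and 13.7 ± 15 CPM in the overexpression libraries, was higher than in controls (adjusted p = 0.00437), a call that limma-voom did not make (adjusted p = 0.109).

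Cholesterol synthesis genes rose, 21 of 23 with 0 lower (camera adjusted p = 5.07e-18). They included Hmgcs1 (0.63 ± 0.05; adjusted p = 6.19e-08), Idi1 (0.61 ± 0.06) and Fdps (0.42 ± 0.04). Genes of the unfolded protein and ATF4 response rose, 14 of 20 (16 adjusted over the list alone) with 1 lower, Xbp1 (−0.23 ± 0.05), at an adjusted p of 1.34e-09. Herpud1 (1.09 ± 0.04; adjusted p = 5.5e-11), Slc7a11 (0.85 ± 0.05) and Pdia4 (0.41 ± 0.03) led them. Targets of p53 rose, 12 of 18 (14 adjusted over the list alone) with 0 lower (adjusted p = 1.76e-08). Among them were Ccng1 (0.55 ± 0.05), Cdkn1a (0.45 ± 0.04), Mdm2 (0.43 ± 0.05) and Trp53inp1 (0.40 ± 0.05).

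Interferon-stimulated genes rose, 17 of 29 (19 adjusted over the list alone) with 0 lower (camera adjusted p = 1.77e-08), by a median of 0.59. The RNA sensor gene Ddx58 (0.93 ± 0.09; adjusted p = 1.91e-06), Parp14 (1.22 ± 0.14) and Oas1a (1.57 ± 0.20) were among them, and Oas1a shares 68.8% of its sequence words, largely with Oas1g. MHC class I antigen presentation genes were higher, 9 of 15 (10 adjusted over the list alone) with 0 lower (adjusted p = 0.00693), with H2-D1 at 0.29 ± 0.06 and the peptide transporter gene Tap2 at 1.12 ± 0.28. Checkpoint ligands and immune recognition genes, 4 of 11 higher and 0 lower (1 lower adjusted over the list alone), were called higher (adjusted p = 0.0242; adjusted p = 0.0837 with an estimated correlation). The galectin gene Lgals9 went from 24.8 ± 0.69 to 53.6 ± 5.6 CPM (SD, n = 3; adjusted p = 1.13e-07) and Nectin2 rose by 0.39 ± 0.08.

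Melanocyte differentiation and pigment genes rose in the overexpression line, 9 of 19 (12 adjusted over the list alone) with 3 lower (camera adjusted p = 2.36e-05). Trpm1 (0.68 ± 0.04; adjusted p = 8.19e-09), the receptor gene Met (0.46 ± 0.03), the tyrosinase gene Tyr (0.45 ± 0.04), whose product is the rate-limiting enzyme of melanin synthesis, and Gpnmb (0.32 ± 0.03) rose. The 3 lower members, named after their values were seen, were the lineage transcription factor genes Mitf (−0.18 ± 0.04), Sox10 (−0.25 ± 0.04) and Pax3 (−0.25 ± 0.04). Genes of dedifferentiated or invasive melanoma fell, 7 of 11 (8 adjusted over the list alone) with 1 higher, Ccn1 (0.49 ± 0.06), at an adjusted p of 5.38e-07. They included Fn1 (−1.98 ± 0.05; adjusted p = 4.3e-13), the N-cadherin gene Cdh2 (−0.94 ± 0.04) and the vimentin gene Vim (−0.47 ± 0.04).

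DNA replication and S phase genes were called higher, 9 of 25 with 1 lower, Pcna at −0.13 ± 0.04 (camera adjusted p = 0.00147), with Mcm2 at 0.69 ± 0.04 and Rrm2 at 0.46 ± 0.03. Lysosome and autophagy genes, 7 of 22 higher and 0 lower (2 lower adjusted over the list alone), were called narrowly (adjusted p = 0.0369; adjusted p = 0.0839 with an estimated correlation). It was lost without control replicate 1 (0.0678), knockdown replicate 1 (0.0508) or overexpression replicate 1 (0.0663). Ribosomal protein genes fell, 21 of 24 (22 adjusted over the list alone) with 0 higher (adjusted p = 4.6e-13), by a median of −0.19, with Rpl7 at −0.38 ± 0.04 and Rps3 at −0.27 ± 0.04. Their share of counts was 4.0% against 4.74% in controls. Mitochondrially encoded transcripts as a list were not called (5 of 13 higher, 0 lower; adjusted p = 0.0755), though they were without knockdown replicate 2 (0.0364) or 3 (0.0325) or overexpression replicate 1 (0.0255). In all 11 of 23 lists were called, 9 higher and 2 lower, and 9 of them held with an estimated correlation. With the transcript length offset 1523 genes were called, and at an adjusted p under 0.01 1883 were.

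**Figure D2:**
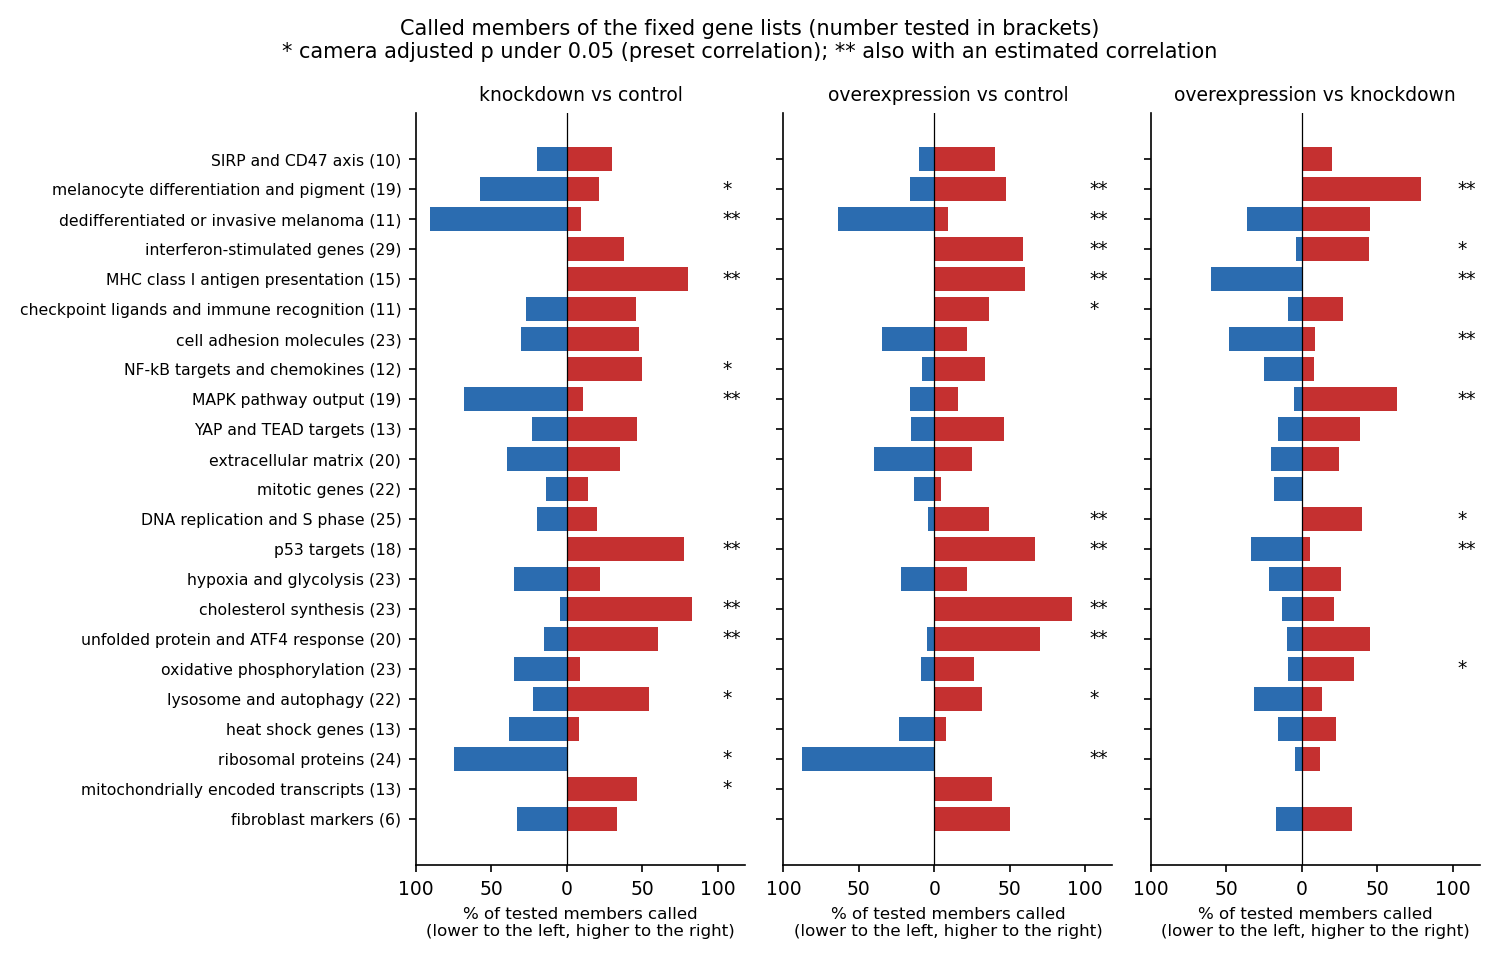
Bars show, for each fixed gene list with at least 5 tested members, the percentage of tested members called lower (to the left) and higher (to the right) in the 3 comparisons, and asterisks mark lists past the camera test. Of 23 cholesterol synthesis genes 19 were higher in the knockdown line and 21 in the overexpression line, whereas 15 of 19 melanocyte genes were higher in the overexpression line than in the knockdown line and 0 were lower.

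Between the overexpression and the knockdown line, the melanocyte and MAPK genes lay apart. Of the 19 melanocyte differentiation and pigment genes 15 were higher with overexpression and 0 lower (camera adjusted p = 1.33e-12). They included Trpm1 (log2 fold change 3.06 ± 0.05, SE, n = 3 per line; adjusted p = 5.22e-17), Slc45a2 (0.63 ± 0.04), Rab27a (0.47 ± 0.04) and Tyr (0.44 ± 0.04). MAPK pathway output genes were higher in 12 of 19 and lower in 1, Phlda1 (adjusted p = 1.22e-06). Etv5 was at 2.16 ± 0.13, Dusp4 at 0.89 ± 0.05, Dusp6 at 0.50 ± 0.05 and the cyclin gene Ccnd1 at 0.45 ± 0.04. Etv5 shares 30.3% of its sequence words, with Gm4798. Against control alone the MAPK list was not called in the overexpression line (3 higher, 3 lower; adjusted p = 0.834). In total 2887 genes (22.1%) differed, 1438 higher and 1449 lower, of which 276 at least 2-fold (181 higher, 95 lower).

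Within the limits set for naming, which leave out low, unseparated and predicted genes, the largest single rises from knockdown to overexpression were the collagen gene Col1a1 (3.76 ± 0.10; 4.95 to 66.5 CPM; adjusted p = 2.11e-13), Adam12 (3.19 ± 0.13) and Trpm1, and the largest falls Coch (−2.74 ± 0.32), Nckap5 (−2.27 ± 0.38) and the semaphorin gene Sema3c (−2.06 ± 0.17; 14.1 to 3.39 CPM). Cell adhesion molecules were lower in 11 of 23 and higher in 2, or 4 adjusted over the list alone (camera adjusted p = 0.000631). L1cam was at −1.65 ± 0.10, Alcam at −0.98 ± 0.09 and Cdh2 at −0.61 ± 0.04 but the integrin gene Itgav at 0.70 ± 0.05. MHC class I genes were lower in 9 of 15 and higher in 0 (adjusted p = 0.000768), with H2-K1 at −0.67 ± 0.09. Targets of p53 were lower in 6 of 18 and higher in 1, or 8 lower adjusted over the list alone (adjusted p = 0.000631), with Trp53inp1 at −0.93 ± 0.05 and Mdm2 at −0.36 ± 0.04.

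Interferon-stimulated genes were higher in 13 of 29 and lower in 1, Gbp2, or 15 and 2 adjusted over the list alone (camera adjusted p = 0.000501; adjusted p = 0.0658 with an estimated correlation), with Isg15 at 1.20 ± 0.19 and Ifit1 at 1.06 ± 0.15. DNA replication and S phase genes were higher in 10 of 25 and lower in 0, or 11 and 2 adjusted over the list alone (adjusted p = 0.0107; adjusted p = 0.11 with an estimated correlation), with Rrm2 at 0.26 ± 0.03. Oxidative phosphorylation genes were higher in 8 of 23 and lower in 2 (adjusted p = 0.00906; adjusted p = 0.307 with an estimated correlation), with Ndufs1 at 0.40 ± 0.04. That call was lost without knockdown replicate 3 (0.0559) or overexpression replicate 1 (0.0735). Of 23 lists 8 were called, 5 higher and 3 lower, and 5 of them held with an estimated correlation. The transcript length offset gave 1372 genes, and an adjusted p under 0.01 gave 1735.

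Of the genes called against control in both perturbed lines, most moved one way. Of 2131 such genes 2012 (94.4%) moved in the same direction, 1142 higher and 870 lower, and 119 in opposite directions, of which 70, Sirpa among them, were lower with knockdown and higher with overexpression and 49 ran the other way. Among the genes moving together the largest shared falls within the limits set for naming were Rasgrp1, Prkg2 and Cdh6 and the largest shared rises Pagr1a, Trim30a and Pla2g3 (1.66 ± 0.30 with knockdown and 1.68 ± 0.30 with overexpression). Both comparisons use the same 3 controls. In 20 simulations all 9 libraries, controls included, were drawn from the mean levels of the controls with no gene changed. They gave a mean of 0.25 genes in the same direction and 0.1 in opposite directions (1 at most for each). As no gene was changed, few were called and overlaps near 0 were fixed in advance. These overlaps do not show what shared controls add where many genes differ. Independent lists of the observed sizes would share 561 and 560.

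The fold changes of all tested genes correlated at 0.646 across genes, which are not independent replicates, against a simulated mean of 0.499 (highest 0.528), and 72.4% of genes had the same sign against 66.7% (highest 67.5%). Their covariance was 0.184 against a simulated 0.0351 (highest 0.0374), a difference of 0.149. The 3 controls are too few to split into groups of at least 2 libraries, so part of the excess may come from the shared controls. Of the 2012 genes 517 (25.7%, against 22.1% of all tested genes) also differed between the perturbed lines, 387 of them further from control in the knockdown line and 130 further in the overexpression line.

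**Figure D3:**
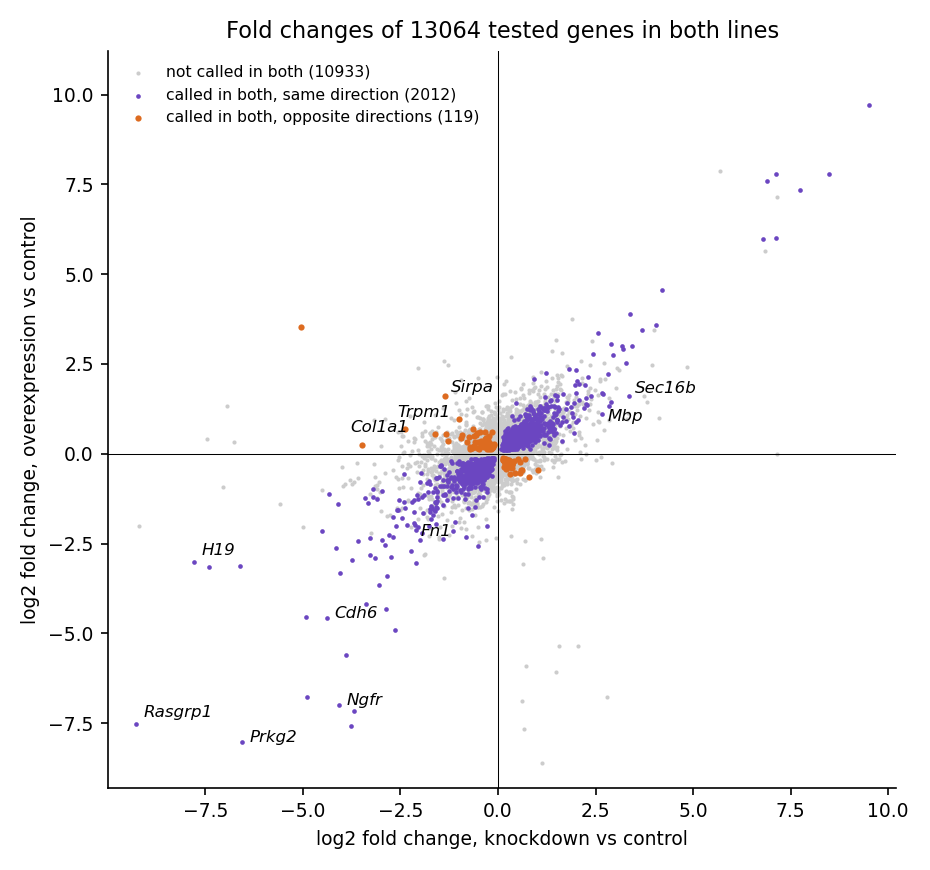
Each point is 1 of 13064 tested genes, with the log2 fold change of knockdown against control on the horizontal axis and of overexpression against control on the vertical axis; 2012 genes called in both lie in the same direction (purple) and 119 in opposite directions (orange). Prkg2 (−6.57 and −8.03) and Rasgrp1 (−9.29 and −7.52) lie at the lower left and Sirpa (−1.36 and 1.61) at the upper left. The values of genes with 0 counts in a group depend on the prior count of the fit and are no bounds.

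Among genes that followed Sirpa, ranked by the smaller of the 2 changes, were Trpm1 (−2.38 ± 0.05 with knockdown and 0.68 ± 0.04 with overexpression) and the gap junction gene Gjb2, which went from 158 ± 4.0 CPM in controls to 108 ± 1.6 and 234 ± 14 CPM (−0.55 ± 0.05 and 0.57 ± 0.05; adjusted p = 2.99e-07 and 3.5e-07). The small GTPase gene Rab17 (−1.33 ± 0.20 and 0.54 ± 0.18; adjusted p = 7.26e-05 and 0.0431) lost its second call without any one of the control or overexpression libraries (0.0616 to 0.135), with the replicate block (0.0601) and with the transcript length offset (0.099). The ectoenzyme gene Cd38 (−0.63 ± 0.22 and 0.69 ± 0.21; adjusted p = 0.0307 and 0.0233) lost its first call without control replicate 1 (0.0538) or 3 (0.156) or knockdown replicate 2 (0.0915), and with limma-voom (0.0605), with the 2 groups alone (0.0649) and with the transcript length offset (0.0702). Its second call was lost without control replicate 1 (0.068) or 2 (0.0933) or overexpression replicate 1 (0.0798) or 2 (0.0816), and with the transcript length offset (0.0749). Against Sirpa ran the lipid transfer protein gene Mttp (0.79 ± 0.11 and −0.64 ± 0.11), the actin-bundling Espn (0.57 ± 0.08 and −0.52 ± 0.09), the contactin gene Cntn1 (1.02 ± 0.10 and −0.46 ± 0.10), Ahnak (0.61 ± 0.11 and −0.45 ± 0.11) and the basement membrane collagen gene Col4a1 (0.59 ± 0.07 and −0.44 ± 0.07). With the transcript length offset the overexpression calls of Cntn1 (adjusted p = 0.097) and Col4a1 (adjusted p = 0.843) ended. The count of 119 fell to 75, 76 and 76 without control replicate 1, 2 or 3, and to 2 with a fold of at least 2 in both, Sirpa and the low-count pseudogene Gm29216, named after its values were seen.

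The median genes of chromosomes 3 and 6 were higher in both perturbed lines. The median gene of chromosome 3 (666 tested genes) stood 0.215 ± 0.012 above the controls in the knockdown line and 0.160 ± 0.010 above them in the overexpression line on the log2 scale (SD of 3 libraries), and that of chromosome 6 (674 genes) 0.163 ± 0.009 and 0.156 ± 0.008. With each chromosome tested as a list among 20, chromosome 3 had camera adjusted p-values of 1.6e-07 and 3.16e-06 and chromosome 6 of 4.67e-06 and 2.15e-07. With an estimated correlation the camera adjusted p-values were 0.00367 and 0.00522 for chromosome 3 and 0.000852 and 0.000373 for chromosome 6. These chromosomes were singled out after the values were seen.

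**Figure D4:**
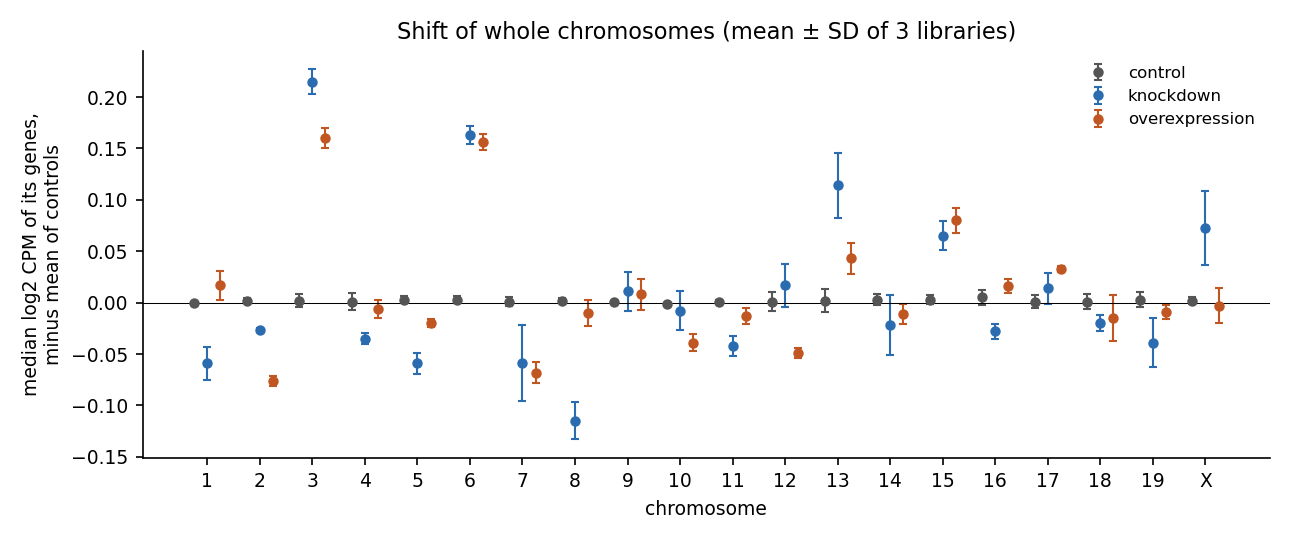
For each tested gene, its mean log2 CPM over the control libraries was subtracted from its log2 CPM in a library. The vertical axis is the median of these differences over the genes of a chromosome, and the horizontal axis the chromosome. Points are means and bars SD of 3 libraries per line. Chromosome 3 stands at 0.215 and 0.160 and chromosome 6 at 0.163 and 0.156 in the knockdown and overexpression lines, while chromosome 8 stands at −0.115 and −0.010.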

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

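Of the tests in this part, all those of the chromosome shifts were chosen only after the result was seen. Those tests covered GC content, neighbouring genes and level of expression. The tests of the covariance from shared controls and of the count of shared genes after GC correction were also chosen only then.

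In the knockdown line Sirpa reads were assigned partly to a transcript that was lower in the other lines. ENSMUST00000099113, which lacks exons 3 and 4 of ENSMUST00000049262 in the annotation used, was at 40.33 ± 5.36 CPM (SD, n = 3) in the knockdown libraries, against 4.23 ± 7.33 CPM in controls and 1.12 ± 1.35 CPM with overexpression. ENSMUST00000049262 was at 0, 52.91 ± 2.03 and 709.52 ± 5.59 CPM in the knockdown, control and overexpression lines and ENSMUST00000103202 at 0, 61.67 ± 15.99 and 31.47 ± 7.96 CPM, but other long forms kept reads in some knockdown libraries. ENSMUST00000103203 was at 38.91 ± 34.59, 73.40 ± 32.09 and 121.37 ± 3.30 CPM and ENSMUST00000179001 at 24.66 ± 28.94, 88.51 ± 16.75 and 0 CPM in the same order, each at 0 in 1 knockdown library. ENSMUST00000099113 was singled out as a signal in single transcripts, which the comparisons of gene totals do not use, above the level in control libraries. The assignment of fragments among near-identical transcripts is uncertain.

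The melanocyte differentiation and pigment list was singled out because it was called lower with knockdown, higher with overexpression and also between the perturbed lines. The last test gave a camera adjusted p of 1.33e-12, with 15 of 19 members higher with overexpression. As that call was part of the rule and uses the same libraries, it is no separate support. The knockdown call behind the choice of this list was lost with an estimated correlation (adjusted p = 0.0119 and 0.179).

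For the counts of changed genes, the 6 libraries of each pair of lines can be split 3 against 3 in 10 ways, which are too few for a share under 0.05. With edgeR, the real split gave 4424 genes for knockdown against control, and the highest of the others gave 1 (224 at an unadjusted p under 0.05). The values were 3535 and 1 (229) for overexpression against control and 2613 and 0 (485) for overexpression against knockdown. In each case 1 of the 10 splits, the real one, gave as many. Every other split mixes both lines on each side, so the line difference itself widens the spread within sides. Low counts there were fixed in advance and do not measure a rate of false calls.

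Genes of chromosomes 3 and 6 were higher in both perturbed lines than in the control line, and a trend with GC content was argued against as the whole source. Genes of above-median GC content had medians of 0.098 and 0.137 (chromosome 3, knockdown and overexpression) and 0.089 and 0.146 (chromosome 6), against 0.257, 0.179, 0.204 and 0.151 in the other genes, so part of the knockdown shift may follow GC content, and after GC correction the medians of all genes were 0.171, 0.160, 0.148 and 0.143, against 0.213, 0.172, 0.153 and 0.148 before. A few strongly changed genes or a single cluster was argued against, because at least 92.3% of windows of 25 neighbouring genes on each chromosome had a median above 0 in each line, against 37.9% (knockdown) and 42.0% (overexpression) of 462 windows elsewhere. Among the latter, chromosome 15 had 80% and 90% and chromosome 13 had 89.5% and 73.7% (knockdown and overexpression), so widespread positive windows were not confined to chromosomes 3 and 6. More copies of both chromosomes would raise genes of low, middle and high expression, and the 12 medians ran from 0.063 to 0.317, but windows ran from −0.065 to 0.495 and −0.148 to 0.376 on chromosome 3 (knockdown and overexpression) and from −0.197 to 0.288 and 0.034 to 0.305 on chromosome 6, so an even gain of either was not shown. A change in copies of all or parts of these chromosomes, in the perturbed lines or in the control line, remains a candidate explanation, found in and tested on the same data, and no DNA measurement was used here.

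Most genes called in both perturbed lines moved the same way although Sirpa moved in opposite directions. Chance values of shared controls at the estimated spread were argued against as the whole source. The covariance of the fold changes was 0.184, above the highest of 20 simulations with no gene changed (0.0374). The simulated controls were redrawn at the estimated spread, so a deviation of the real control libraries beyond that spread was not covered. A trend with GC content was argued against too, since 2161 genes shared a direction after its removal, against 2012 before. For the 1495 of the 2012 genes not called between the perturbed lines, a difference of the control line alone cannot be told apart from a response common to both. Such a difference could have arisen while the lines were made, and each condition is 1 line. The other 517 (25.7%, against 22.1% of all tested genes) also differed between the perturbed lines. That argues against a difference of the control line alone as the whole source for those 517 genes. No biological explanation can be preferred on these data.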

How the results depend on the processing

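Of the alternatives below, GC correction and leaving out chromosomes 3 and 6 were chosen after seeing the data, and every alternative set beforehand was run. The Sirpa changes held under every alternative, at −1.37 to −1.33 (knockdown) and 1.60 to 1.63 (overexpression) with 1 library left out and −1.15 and 1.53 with the transcript length offset. With the transcript length offset the counts were 2771 (knockdown), 1523 (overexpression), 1372 (overexpression against knockdown), 47 (opposite directions) and 938 (same direction). The common coefficient of variation between libraries rose from 0.097 to 0.165 under that offset. Fold changes moved too, for example that of Col4a1 with overexpression to −0.07, and how much each lowered the counts was not tested. An adjusted p under 0.01 gave 1883, 1735, 54 and 1203 for overexpression, overexpression against knockdown, opposite and same directions, and a log2 fold change of at least 1 gave 603, 288, 276, 2 and 178 in the order above, each by construction. Leaving out 1 library gave 3885 to 4555, 2440 to 3297 and 2241 to 2867 calls, 75 to 121 genes in opposite directions (75, 76 and 76 without control replicate 1, 2 or 3) and 1564 to 1971 in the same direction, with fewer samples to test. Lists called numbered 10 to 12, 10 to 13 and 7 to 9 with 1 library left out. They numbered 6 (knockdown) and 5 (overexpression against knockdown) with an estimated correlation, and 20, 18 and 16 with fry, which asks whether the members move one way and not whether they differ from other genes. The replicate numbers did not consistently pair the samples. Of 9 same-number correlations, from −0.093 to 0.127, 1 was over 0.1, and 0 of 9 libraries correlated best with their own number in both other lines. The highest, 0.127, joined knockdown replicate 1 and overexpression replicate 1, each the best match of the other. The replicate block gave 4423, 2957 and 2712 calls, 110 and 1885 in opposite and same directions, Sirpa at −1.36 and 1.61, and 10, 11 and 8 lists. GC correction gave 4728, 3380 and 2927 calls, 130 and 2161 in opposite and same directions. Without chromosomes 3 and 6, whose genes are then not tested, the values were 3969, 2600, 2537, 96 and 1642. Of 310 called results of named genes 58 lost their call under at least 1 alternative, 170 of 5853 tests, and 0 of them reversed. Of the results that were not called, Vwf between the perturbed lines reversed with the transcript length offset, to 2.35 (adjusted p = 0.0196), and the cause was not tested. The self-test recovered 55.6% of 1.5-fold changes for knockdown and 70.8% for overexpression.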

Other observations

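The tests of single chromosomes and the level limits for genes present in 1 line only were chosen only after the result was seen, and the other tests in this part were set beforehand.

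Several gene groups moved in both directions within a list. In the knockdown line the cell adhesion molecules split into 11 of 23 higher and 7 lower (8 lower adjusted over the list alone; camera adjusted p = 0.286). L1cam (1.47 ± 0.10) and Alcam (1.24 ± 0.09), both immunoglobulin-type adhesion molecules, rose and the integrin gene Itga3 fell (−2.45 ± 0.21). With overexpression 5 were higher and 8 lower (7 and 8 adjusted over the list alone; adjusted p = 0.198), with Cdh2 and Mcam (−0.46 ± 0.05) falling. Extracellular matrix genes were 7 higher and 8 lower of 20 with knockdown (8 and 8 adjusted over the list alone; adjusted p = 0.466) and 5 and 8 with overexpression (5 and 9 adjusted over the list alone, camera adjusted p = 0.103). Col1a1 was at −3.50 ± 0.10 in the knockdown line, with Col5a1 lower in both (−1.25 ± 0.06 and −1.04 ± 0.06) and Lamc1 higher in both (0.90 ± 0.05 and 0.67 ± 0.05). Between the perturbed lines 5 were higher and 4 lower (6 and 5 adjusted over the list alone; adjusted p = 0.796). The immune recognition genes in the knockdown line were 5 higher and 3 lower of 11 (adjusted p = 0.466). Cd276 (−1.28 ± 0.11) and the galectin gene Lgals3 (−0.63 ± 0.07) were lower and Lgals9 (0.70 ± 0.09) and Nectin2 (0.52 ± 0.08) higher. Of the same list 3 were higher and 1 lower between the perturbed lines (4 and 1 adjusted over the list alone; adjusted p = 0.351). Within the SIRP and CD47 axis, Ptpn6, the phosphatase recruited by Sirpa, rose in both lines (0.62 ± 0.12 and 0.60 ± 0.12) and Skap2 fell in both (−0.26 ± 0.06 and −0.35 ± 0.06). That list of 10 had 3 higher and 2 lower with knockdown (3 and 3 adjusted over the list alone; adjusted p = 0.697). It had 4 and 1 with overexpression (adjusted p = 0.0575) and 2 and 0 between the lines (adjusted p = 0.0946). With overexpression it was called under the filter of 1 CPM in 3 libraries (0.032) and without control replicate 2 (0.0361) or overexpression replicate 2 (0.0399) or 3 (0.0415).

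The cell cycle lists were not called with knockdown. Mitotic genes were 3 higher and 3 lower of 22 (camera adjusted p = 0.999), with Mki67 at 0.39 ± 0.04. DNA replication and S phase genes were 5 and 5 of 25 (adjusted p = 0.47), with Mcm2 at 0.60 ± 0.04. Mitotic genes were 1 and 3 with overexpression (adjusted p = 0.313) and 0 and 4 between the lines (0 and 3 adjusted over the list alone; adjusted p = 0.442). Hypoxia and glycolysis genes were 5 and 8 of 23 with knockdown (adjusted p = 0.37). They were 5 and 5 with overexpression (6 and 6 adjusted over the list alone; adjusted p = 0.868), with the lactate transporter gene Slc16a3 at −0.92 ± 0.10, and 6 and 5 between the lines (8 and 6 adjusted over the list alone, camera adjusted p = 0.442). Oxidative phosphorylation genes were 2 and 8 of 23 with knockdown (adjusted p = 0.17) and 6 and 2 with overexpression (adjusted p = 0.287). Heat shock genes were 1 and 5 of 13 with knockdown (2 and 6 adjusted over the list alone; adjusted p = 0.079, and 0.043 without knockdown replicate 1), with Hspb8 at −2.70 ± 0.21. They were 1 and 3 with overexpression (adjusted p = 0.0888) and 3 and 2 between the lines (adjusted p = 0.648). YAP and TEAD targets were 6 and 3 of 13 with knockdown (7 and 3 adjusted over the list alone; adjusted p = 0.34) and 6 and 2 with overexpression (adjusted p = 0.0575). The latter was called without overexpression replicate 2 (0.0413) or 3 (0.0375). They were 5 and 2 between the lines (5 and 3 adjusted over the list alone, camera adjusted p = 0.512), with Crim1 at 1.30 ± 0.07 and 0.71 ± 0.07 in the perturbed lines.

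Of the remaining results, NF-kB targets were 4 higher and 1 lower of 12 with overexpression (4 and 2 adjusted over the list alone; camera adjusted p = 0.449) and 1 and 3 between the lines (1 and 5 adjusted over the list alone, camera adjusted p = 0.0507). Between the lines the dedifferentiated list was 5 and 4 of 11 (7 and 4 adjusted over the list alone; adjusted p = 0.456). There cholesterol synthesis genes were 5 and 3 (5 and 4; adjusted p = 0.351) and the unfolded protein and ATF4 response 9 and 2 (9 and 5; adjusted p = 0.0946). Lysosome and autophagy genes were 3 and 7 (4 and 9; adjusted p = 0.442), ribosomal proteins 3 and 1 (adjusted p = 0.442) and mitochondrial transcripts 0 and 0 (adjusted p = 0.192, and 0.0387 without knockdown replicate 2). Fibroblast markers were 2 and 2 of 6 with knockdown (adjusted p = 0.999), 3 and 0 with overexpression (adjusted p = 0.191) and 2 and 1 between the lines (adjusted p = 0.442). Of the lists too small to test, the endothelial gene Eng was expressed in all lines (271, 361 and 299 CPM in control, knockdown and overexpression). It was called higher in both lines against control. The overexpression call was lost without control replicate 2 (edgeR adjusted p = 0.0549) or 3 (0.155) or overexpression replicate 2 (0.125) or 3 (0.0638), and with the transcript length offset (0.146). The T and NK gene Lck averaged 2.02, 0.713 and 2.20 CPM and the epithelial gene Cdh1 1.41, 0.590 and 0.863 CPM. Lck was called lower with knockdown and higher with overexpression than with knockdown. Its knockdown call was lost under several alternatives, for example without control replicate 2 (edgeR adjusted p = 0.111) or knockdown replicate 2 (0.115). The myeloid gene Cd68 averaged 1.88, 2.78 and 1.05 CPM and was called lower with overexpression than with knockdown. That call was lost without knockdown replicate 2 (edgeR adjusted p = 0.0684) or overexpression replicate 1 (0.0967) or 3 (0.0737). Median, mean and test differed in sign for the SIRP list (median 0.02, mean −0.02, tested lower), YAP targets (0.18, −0.02, higher) and fibroblast markers (0.14, −0.30, lower) with knockdown. The same held for NF-kB targets (0.14, −0.03, higher), MAPK output (−0.01, 0.07, higher) and adhesion molecules (0.01, −0.11, lower) with overexpression. Between the lines it held for hypoxia genes (0.04, −0.02, higher) and heat shock genes (−0.01, 0.12, higher).

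Some other chromosomes were called against control in 1 line with the preset correlation, and of these only chromosome 8 was also called between the lines. Chromosome 8 was at −0.115 ± 0.018 (SD of 3 libraries) in the knockdown line (camera adjusted p = 0.00135) and −0.010 ± 0.013 in the overexpression line, a difference with an adjusted p of 0.000452. Chromosome 13 was at 0.114 ± 0.032 in the knockdown line (adjusted p = 0.0127). In the overexpression line chromosome 2 was at −0.076 ± 0.005 (adjusted p = 0.00629), chromosome 15 at 0.080 ± 0.012 (adjusted p = 0.0352) and chromosome 7 at −0.068 ± 0.010 (adjusted p = 0.039; adjusted p = 0.153 with an estimated correlation). Chromosomes 15 and 7 were at 0.065 ± 0.014 (adjusted p = 0.127; adjusted p = 0.0107 with an estimated correlation) and −0.059 ± 0.037 (adjusted p = 0.127) in the knockdown line, and were not called between the lines (adjusted p = 0.957 and 0.933). With an estimated correlation chromosomes 2 (camera adjusted p = 0.0388) and 5 (0.0349) were also called with knockdown and chromosome 10 (0.0262) with overexpression. Chromosomes 2 (0.000373) and 15 (0.0041) were called with overexpression under that setting too, so each was then called in both lines.

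A few genes were present in one line and near absent in another, with every library of one line under 0.5 CPM and a mean of at least 5 CPM in the other. Against control these were H19, Rasgrp1 and the predicted gene Gm6565 (0 CPM in controls, 5.02 CPM with knockdown) in the knockdown line, and Ngfr, Rasgrp1, Cdh6, Gm31517 and Gm6565 (5.75 CPM) in the overexpression line. Between the perturbed lines they were Gm10221 (5.2 CPM with knockdown) and Gm2223 (5.78 CPM), both at 0 with overexpression.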
